A study of Mus musculus with 3 samples.

How the data were processed

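The series holds 3 samples of mouse embryonic stem cells: an input library, a DMSO FAIRE sample and an ICRF-193 FAIRE sample. Per the labels' protocols, feeder-free cells were seeded in 10 cm dishes, the medium was replaced at 24 h, and treatment with 500 nM ICRF-193 or DMSO began at 32 h and lasted 16 h. FAIRE libraries were made with a standard ChIP-seq library protocol for Illumina sequencing, per the labels' protocols. Groups were taken from the sample titles. The titles of both FAIRE samples name replicates 1 and 2 together, so there was 1 sample in each group.

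The processed data analysed were 1 list of intervals of the whole series. The submitters' processing notes name Bowtie, without a version, and the mouse build mm9. The name of the list names F-Seq, a program that smooths aligned reads into a density along the genome and lists the intervals where the density exceeds a threshold, and calls the intervals potential peaks. The F-Seq settings, the read filters, the use of the input library and which of the 3 samples entered the list are not given in the sources used here. The list has 5 columns without a header: chromosome, start, end, a running name and a score. Each score is the authors' deposited value for its interval, and its scale is not given in the sources used here. The scores were used to rank, filter and describe intervals within the list. Under Other observations, ratios of scores between chromosomes were also set against ratios of DNA dose. Those comparisons assume that scores are proportional to DNA dose, which was not tested. Starts in the list count from 0, and coordinates are printed counted from 1.

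Because the list does not separate the conditions, the planned comparisons of DMSO with ICRF-193 (the share of overlapping peaks and the change per peak) were not run. The 3 planned results on gene promoters and 13 gene lists needed a gene annotation of mm9 and were not run either. A table of gene names of assembly GRCm38.p6 was at hand and was not used, because its build differs and coordinates were not converted. For the same reason GC content, mappability and gene content were not measured.

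Intervals, widths, scores and gaps were summarised with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1. The span of a chromosome ran from its first to its last interval, since chromosome lengths were not taken from elsewhere. Density was the number of intervals per Mb of span, and each chromosome was expressed relative to the median of the 19 autosomes. A pair of 95% intervals was computed for densities: an exact Poisson interval, and a percentile interval from 1000 resamples of the chromosome's 5 Mb blocks, which allows for clustering. Clustering was measured as the median distance between neighbouring midpoints and compared with 100 placements of the same number of intervals at uniformly random positions in each chromosome's span. No test between conditions was possible, and no p-value is given. The procedures were tested on simulated intervals placed on the real spans. A density fold set to 2 on chromosome 8 was recovered as 2.01 among 99211 simulated intervals. A score scale set to 0.5 on chromosome X was recovered as 0.494 among 89230. Unclustered intervals gave an observed-to-random spacing ratio of 0.995 among 94529. The score scale was recovered at a lower density than the 5, 10 and 20 intervals per Mb used on the list. That simulation therefore does not test scores close to the lowest score of the list.

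The regions named were fixed by a rule written before the data were examined: without an mm9 annotation, the 5 highest-scoring and the 5 widest intervals, the 5 windows of 1 Mb with the most intervals, and the 3 longest stretches with no interval. Alternatives fixed at the same time were a stricter score threshold (intervals at or above the median, or the top 10%), joining intervals within 500 bp, a minimum width of 200 bp, leaving out chromosome Y and the mitochondrial genome, leaving out the top 0.1% by score, measuring density in covered bases, leaving empty 1 Mb windows out of the span, and restricting random placement to occupied windows. Joining before measuring density and leaving out the densest 5% of windows were added after seeing the data.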

Results

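FAIRE-seq was used to map open chromatin in mouse embryonic stem cells (mESCs) of a mixed 129Sv and C57Bl/6 strain background. FAIRE (formaldehyde-assisted isolation of regulatory elements) recovers DNA that is poorly crosslinked to protein, which is enriched for nucleosome-depleted DNA such as active promoters and enhancers. The series comprised 3 samples. These were an input library of genomic DNA from the stem cells, a FAIRE sample of cells given the solvent DMSO, and a FAIRE sample of cells given 500 nM ICRF-193. ICRF-193 inhibits the catalytic activity of topoisomerase II, the enzyme that passes 1 DNA duplex through another. Both treatments lasted 16 h. The title of each FAIRE sample places replicates 1 and 2 in that sample, so each group was represented by 1 sample. The series' description gives the role of Top2a catalytic activity in transcription as its subject.

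A single list of potential FAIRE peaks was analysed. It assigned no interval and no score to a sample, so it was treated as 1 pooled list without replicates. The comparison of DMSO with ICRF-193 was therefore not made here, and no value below describes an effect of the inhibitor. The read depth behind the intervals is unknown. Intervals are located by their mm9 coordinates and were not assigned to genes, because an mm9 gene annotation was not used here.

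The list held 348759 non-overlapping intervals on 22 sequences, which together covered 40.3 Mb. The intervals covered 1.64% of the 2415 Mb spanned by the 19 autosomes. Most of the intervals were narrow and lay just above the lowest score in the list. The median width was 41 bp (interquartile range 7 to 163 bp), and 107424 intervals, 30.8% of the total, were no wider than 10 bp. A width of a single base pair was found for 18648 intervals. The median score was 0.0137, against a lowest score of 0.0129, and 58.3% of intervals scored within 10% of that lowest value. The lowest score was almost identical on each autosome and on chromosome X, from 0.0128653 to 0.0128656. The 99th percentile of the score was 0.0456, or 3.55 times the lowest score.

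Wide intervals carried most of the covered sequence. The 69999 intervals of at least 200 bp made up 20.1% of the list and 66.8% of the covered bases, and their median score was 0.0235. The high-score intervals, defined as the top 10% by score, numbered 34876. They had a median width of 371 bp and held 40.9% of the covered bases. The 174379 low-score intervals, defined as those below the median score, had a median width of 7 bp and held 5.46% of the covered bases. Score and width were closely related across intervals (Spearman's rho = 0.94), although intervals are not independent replicates. F-Seq lists stretches where a smoothed density exceeds a threshold, so this relation is in part a property of the program's output. Neighbouring intervals were often separated by only a few bases. Of the 348737 gaps between neighbours on a chromosome, 34.0% were no longer than 20 bp. Joining intervals within 500 bp of each other left 160807 regions with a median width of 166 bp, and 51.5% of these regions held 1 interval.

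Interval density differed between chromosomes, and chromosome X stood far below the autosomes. The 19 autosomes had 142 ± 30.8 intervals per Mb (SD over autosomes, n = 19), with a median of 139. Chromosome 11, which is among the gene-rich mouse chromosomes, was the densest with 215 intervals per Mb. That was 1.54 times the autosomal median (95% block interval 1.19 to 1.91). Gene content was not measured here. Chromosome 8 followed with 197 per Mb, or 1.42 times the median (1.13 to 1.73). Chromosome 12 was the sparsest autosome with 99.8 per Mb, or 0.72 times the median (0.55 to 0.90). Chromosome X had 23.4 intervals per Mb, which was 0.17 times the autosomal median (0.10 to 0.29) and 3.86 autosomal SDs below the autosomal mean. The block intervals come from resampling 5 Mb blocks of each chromosome. Exact Poisson intervals were much narrower, 22.6 to 24.1 per Mb for chromosome X and 212 to 217 for chromosome 11. They cover counting error only.

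**Figure D1:**
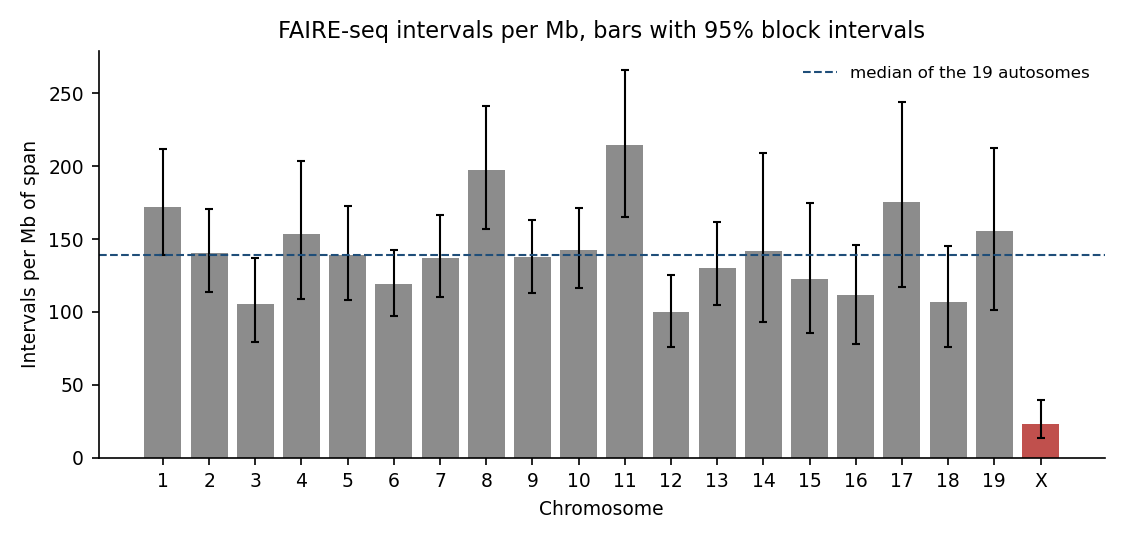
Intervals per Mb of span (vertical axis) for the 19 autosomes (grey) and chromosome X (red). Error bars are 95% intervals from resampling 5 Mb blocks, and the dashed line is the autosomal median of 139 per Mb. Chromosome 11 is the tallest bar at 215 and chromosome X the shortest at 23.4.

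The order of the chromosomes depended in part on the score of the intervals. Chromosome 11 was enriched to a similar extent among low-score intervals (1.58 times the autosomal median) and high-score intervals (1.57 times). On chromosome 8 the excess was 1.5 times among low-score intervals and 1.24 times among high-score intervals. Chromosome 1 had 172 intervals per Mb, with 1.34 times the autosomal median of low-score intervals, while its density of high-score intervals was the autosomal median itself, 14.2 per Mb. Chromosome 7 showed the opposite order, with 0.98 times the median for low-score and 1.14 times for high-score intervals. Chromosome X was depleted in both classes, with 0.13 times the median for low-score and 0.24 times for high-score intervals. The relative density of low-score intervals divided by that of high-score intervals was 1.34 on chromosome 1 (95% block interval 1.21 to 1.46), 1.23 on chromosome 14 (1.01 to 1.46), 1.21 on chromosome 8 (1.06 to 1.38), 1.01 on chromosome 11 (0.94 to 1.1) and 0.86 on chromosome 7 (0.77 to 0.96). Chromosomes 12, 16 and 18 also had intervals above 1, at 1.09 to 1.13. On chromosome X it was 0.54 (0.40 to 0.93), and 0.79 (0.65 to 1.02) without the 3 windows from 120000001 to 123000000, which held 33.4% of the intervals of that chromosome. Those windows were chosen after their values were seen, and the autosomes were left whole.

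**Figure D2:**
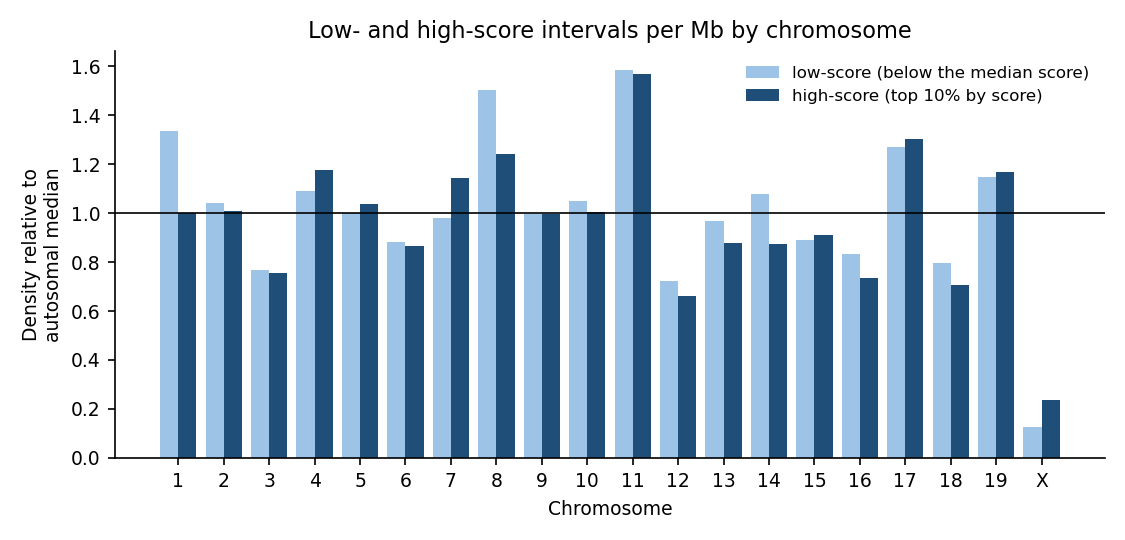
Density of low-score intervals (light) and high-score intervals (dark) on each chromosome, relative to the autosomal median of the same class (horizontal line at 1). Chromosome 8 reads 1.5 and 1.24, chromosome 1 reads 1.34 and 1.0, and chromosome X reads 0.13 and 0.24.

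The sequences outside the autosomes and chromosome X contributed few intervals. On chromosome Y 156 intervals were listed between positions 346723 and 2902553. Of these, 55 were high-score intervals. The mitochondrial genome was listed as 1 interval of 16299 bp, its entire length, with a score of 22.6.

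Intervals were strongly clustered along the chromosomes. The median distance between the midpoints of neighbours was 530 bp. In 100 random placements of as many intervals on the autosomes and chromosome X the median distance was 4788 bp, and the placements ranged from 4769 to 4803 bp. Neighbours thus lay 9.03 times closer than random placement gave. After joining within 500 bp, neighbours still lay 2.25 times closer than random. Across 2425 autosomal windows of 1 Mb the median was 92 intervals per window, with a 10th percentile of 15 and a 90th percentile of 335. The variance of the window counts was 151 times their mean, against at most 7.48 times in the random placements. The densest 10% of windows held 33.0% of the autosomal intervals.

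The 5 densest windows of 1 Mb lay on chromosomes 4, 17 and 14. On chromosome 4, the adjoining windows 145000001 to 146000000 and 146000001 to 147000000 held 1323 and 1280 intervals, 14.4 and 13.9 times the median window, and intervals covered 33.9% and 32.6% of their bases. High-score intervals made up 17.3% and 17.2% of these intervals. The window 30000001 to 31000000 of chromosome 17 held 1275 intervals covering 25.4% of its bases, of which 8.78% were high-score. The windows 7000001 to 8000000 and 4000001 to 5000000 of chromosome 14 held 1120 and 1035 intervals. They differed from those of chromosome 4 in composition, with 5.63% and 6.67% high-score intervals, and in coverage, with 12.6% and 14.2% of bases covered. Whether reads of repeated sequence or extra copies gave the counts of these 5 windows was not tested. Those counts are therefore not a measure of open chromatin.

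**Figure D3:**
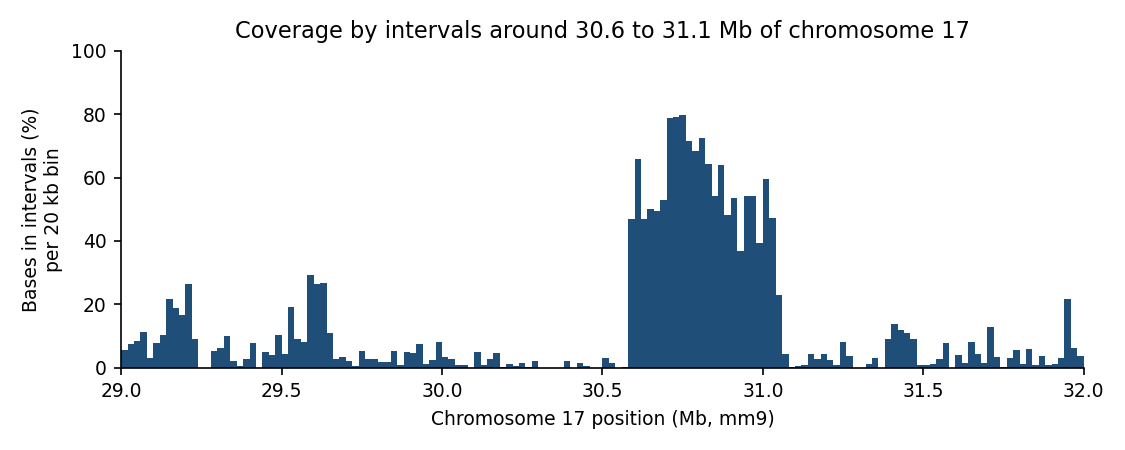
Percentage of bases covered by intervals in 20 kb bins (vertical axis) along chromosome 17 from 29 to 32 Mb (horizontal axis, mm9). Coverage is between 23.1% and 79.8% in each bin from 30580001 to 31060000 and is at most 13.8% in the 24 bins on either side of that stretch. Farther to the left, single bins reach up to 29.4%.

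The highest scores belonged to a few intervals. Only 30 intervals scored above 1. The 5 highest were on chromosomes 2, 12 and 9. Chromosome 2 held the first and second, at 98506011 to 98507944 (score 2049, or 150064 times the median score) and 98501933 to 98504603 (score 800). The interval at 3109445 to 3110524 of chromosome 12 scored 585. On chromosome 9 the interval at 35112404 to 35113628 scored 290, and the interval at 3000001 to 3038644 scored 152. The last of these was also the widest interval of the list, at 38644 bp, and its first base was the first position listed on chromosome 9. The next widest lay on chromosome 11 at 3051933 to 3080388 (28456 bp), on chromosome Y at 2874340 to 2902553 (28214 bp), on chromosome 8 at 19712050 to 19739148 (27099 bp) and on chromosome 11 at 3025144 to 3049060 (23917 bp). Their scores were between 0.127 and 0.472, or 9.28 to 34.6 times the median score. Whether reads of repeated sequence gave the highest scores or the widest intervals was not tested, so neither is a measure of open chromatin.

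Of 15 stretches of at least 1 Mb without an interval, 8 were on chromosome X, with 10.9 Mb in all, and 7 on autosomes, with 17.3 Mb in all. The longest was at 39350998 to 46435641 of chromosome 7 (7.08 Mb). It was followed by 127667477 to 130112679 of chromosome X (2.45 Mb) and 20038081 to 22043656 of chromosome 8 (2.01 Mb). Whether reads could be aligned in these stretches was not tested, so the absence of intervals there is not a measure of closed chromatin.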

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

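The number of intervals depended on the processing. It was 174380 at or above the median score and 34876 in the top 10% by score, against 348759 in the list. Both score filters keep a fixed share of the list by definition. The number was 69999 with a minimum width of 200 bp and 160807 after joining within 500 bp. The covered sequence fell to 16.5 Mb in the top 10% and otherwise stayed within 1.5 times of 40.3 Mb. The fold by which neighbours lay closer than random was 3.70 at or above the median score, 2.53 in the top 10% and 2.25 after joining, against 9.03. Joining merges intervals a few bases apart, which lowers the fold by construction. Why the score filters lowered it was not tested. The density of chromosome 1 was 1.0 times the autosomal median in the top 10% by score, against 1.24 times in the list and a block interval of 1.0 to 1.52. Of 54 alternative values for 11 results, 45 stayed within their interval or within 1.5 times of the reported value. Another 9 moved and 0 changed direction. The 9 include the numbers of intervals under both score filters, which were fixed by definition. The densities of chromosomes 8, 11, 12, 17 and X relative to the autosomal median stayed within their block intervals under each alternative. Leaving out the densest 5% of windows was an alternative chosen after seeing the data. It gave 1.19 for chromosome 8, 1.05 for chromosome 17, 1.04 for chromosome 1 and 0.15 for chromosome X. Alternatives for the comparison of DMSO with ICRF-193, for promoters and for gene lists were not run, because the list does not separate the samples and an mm9 annotation was not used. No replicate could be left out. The unknown read depth limits what a missing interval can show.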

Other observations

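The tests in this part were chosen after the patterns had been seen, and no biological explanation was set against a group of the design, since the list does not separate the groups. A scan for stretches in which at least 10 consecutive 20 kb bins were each at least 20% covered by intervals found 7 stretches among 128928 bins, of which the median bin had no interval. The longest was 480 kb, at 30580001 to 31060000 of chromosome 17, with 1334 intervals and a mean coverage of 56.7%. Chromosome 4 held 2, at 146600001 to 147040000 (46.4% covered) and 145540001 to 145780000 (55.8%). Chromosome 1 held 2, at 84940001 to 85340000 (62.9%) and 87340001 to 87560000 (64.3%). Chromosome 8 held 2, at 19840001 to 20040000 (86.7%) and 71940001 to 72140000 (44.9%).

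Wide intervals concentrated beside long empty stretches and chromosome ends. Of the 100 widest intervals on the autosomes and chromosome X, each at least 3451 bp, 54 lay within 500 kb of the first or last interval of a chromosome or of a stretch of at least 1 Mb without an interval. Among all intervals 1.49% did. Of the 100 highest-scoring intervals 15 did. On chromosome X, 3 adjoining windows from 120000001 to 123000000 held 1275 of its 3817 intervals, or 33.4%.

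The filled stretch of chromosome 17 may reflect extra copies of the stretch relative to the mm9 reference or many separate open regions close together, and the list does not decide between them. Its least covered 20 kb bin was 23.1% covered, whereas the most covered of the 24 bins on either side reached 13.8%. The scan admitted only bins at least 20% covered, so a bin inside at the level of the flanks was ruled out beforehand. This contrast therefore supports neither explanation. Farther to the left, beyond those flanks, the bin at 29.58 Mb was 29.4% covered, above the least covered bin inside. Coverage stepped from 0.17% to 46.9% at the left edge and fell more gradually at the right edge, through 47.4% and 23.1% to 4.51%. Whether any extra copies belong to the strain, arose in culture or are reads of repeated sequence placed there by the aligner was not tested.

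Chromosome 8 held an excess of low-score intervals, for which an extra copy of the chromosome in some of the cells is a candidate explanation, since gain of chromosome 8 is a known change in cultured mouse embryonic stem cells. It was not alone in this. The relative density of low-score intervals also exceeded that of high-score intervals, with block intervals above 1, on chromosomes 1, 12, 14, 16 and 18. On chromosomes 12, 14 and 16 the lower ends were close to 1, at 1.02, 1.01 and 1.01. Chromosomes 1 (1.34 times) and 14 (1.23) were above chromosome 8 (1.21). In 1 Mb windows with 5 to 15 high-score intervals, its low-score count was a median of 1.35 times that of other autosomes' windows with as many high-score intervals (95% block interval 1.1 to 1.70, 33 windows), against 0.79 to 1.18 for the other autosomes, and chromosome 1 was the highest of these at 1.18 (1.09 to 1.38). More open chromatin on chromosome 8 stays open because the interval of that chromosome reaches the other autosomes. Without the densest 5% of windows the ratio was 1.31 (1.0 to 1.70), but 32 of the 33 matched windows remained. That value therefore hardly tests whether a few dense windows gave the excess, which stays open. Over the whole chromosome, density was 1.19 times the autosomal median without the densest 5% of windows, against 1.42 times with them. The centromeric side was at 1.31 times (0.58 to 1.74) and the telomeric side at 1.42 (1.0 to 1.94), and since both intervals also reach the other autosomes, these values do not decide for a gain in some of the cells. A copy gained in all cells is argued against if scores follow DNA dose and the chromosome otherwise lies within the autosomal range. Its score at a density of 10 intervals per Mb was 1.11 times the autosomal median (1.0 to 1.21). That was below the 1.28 that even the lowest autosome would reach with 1.5 times the dose. Chromosome 11 had the highest such score of the autosomes, 1.16 times the median, and a copy gain there was not tested.

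The low density of chromosome X may reflect a single copy per cell, which would give 0.5 times the autosomal DNA dose, but this was not settled. Chromosome Y held 156 intervals, 55 of them high-score, as cells with a chromosome Y and a single chromosome X would give. Whether reads of repeated sequence gave those intervals was not tested. Scores inform on the dose of chromosome X only if they follow DNA dose. The score of chromosome X at a density of 10 intervals per Mb was 0.58 times the autosomal median (95% block interval 0.49 to 0.76). Halving the autosomes' values gives a range of 0.43 to 0.58. To more digits, chromosome X at 0.5793 lay just above the upper limit of 0.5786, which its block interval includes. Without the windows from 120000001 to 123000000 the score of chromosome X was 0.50. The lowest score in the list stood at 0.48 on this scale, so the lower part of the range could not be reached, and 0.50 lies just above that floor. At 5 intervals per Mb it was 0.62 (0.48 to 0.82) against a range of 0.44 to 0.57, and 0.51 without those windows, with the lowest score at 0.39. At 20 intervals per Mb it was 0.64 (0.63 to 0.74) against 0.43 to 0.61, but there the lowest score already stood at 0.63, so that value could not fall within the range. Of the autosomal intervals 8.05% scored at least 2 times the lowest score. Chromosome X kept 0.17 times the autosomal density, or 0.11 times without those windows. The autosomes were left whole in that comparison and in the scores and ratios of chromosome X without those windows. Leaving the densest 5% of windows out of all chromosomes gave 0.15 times. A halved dose alone would leave about 8.05% only if scores follow DNA dose and each such interval stays a single interval. It also requires that chromosome X otherwise lies within the autosomal range. These conditions were not tested, so the contrast does not decide on a halved dose. A constant share of sites lost whatever their score, such as sequence where reads cannot be aligned, predicts equal depletion of both score classes. The ratio of the low-score to the high-score relative density was 0.54 (0.40 to 0.93), but 0.79 (0.65 to 1.02) without those windows, so this ratio alone does not decide. In the 15 windows with 5 to 15 high-score intervals, the low-score count was a median of 0.30 times that of autosomal windows with as many (0.17 to 0.38), and none was above 1, against 0.79 to 1.18 for the autosomes other than chromosome 8. Choosing windows by their high-score intervals lowers this ratio on a sparse chromosome, but autosomes thinned at random to 0.17 times their density gave 0.50 to 1.27 in 380 draws. Thinning to 0.24 times their density, or losing whole stretches of 10 to 1000 kb at either share, gave no value below 0.40. Constant loss that keeps 0.17 or 0.24 of the intervals is therefore argued against as the only cause. The 15 windows held 13.3% of the intervals of chromosome X and included none of the windows from 120000001 to 123000000. Outside those windows chromosome X kept 0.11 times the density of autosomes left whole, and loss at that share was not run. The median of the randomly thinned draws was 0.84 at 0.24 times and 0.72 at 0.17 times, so it fell with the share kept. Constant loss at 0.11 times, or a partial contribution of constant loss, therefore stays open.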
